A study of Aplysia californica with 3 samples.

How the data were processed

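Gene expression was compared between the L7 neuron and a sensory cluster of the sea hare Aplysia californica on 3 2-colour Agilent oligonucleotide arrays. L7 is an identified motor neuron of the abdominal ganglion. Each array carried RNA of L7 labelled with Cy3 (green) and RNA of the sensory cluster labelled with Cy5 (red), and the labels describe the 3 arrays as biological replicates. The dyes were not exchanged on any array, so a dye effect cannot be told apart from a difference between the cells. Per the labels' protocols, neurons were fixed in ethanol, and total RNA was extracted with RNAqueous kits, amplified linearly in 1 round and labelled as cRNA by a direct or an indirect method, and the method used for each array is not given in the sources used here.

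The deposited scanner tables give, for each spot, the mean signal intensity and the local background intensity of each dye, processed intensities, a log10 ratio of red over green, and flags for outlier, saturated and background-level spots. Per the file headers, array 1 was read with Feature Extraction A.7.5.1. The tables of arrays 2 and 3 have no settings block, and their version and settings are not given in the sources used here. The deposited series values are the log10 ratios of red over green from the same scanner tables. They matched those ratios by feature number to within 0.005 on each of 41991 measured features, with column medians of 0.003, −0.006 and 0.000, so that their scale and direction were settled by the match and no further centring had been applied. Their largest absolute value was 2, at which the ratios are limited.

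Each array held 44247 features, of which 2256 were control features. The measured features held 21128 probes for 14412 targets. Target names were taken from the name column of the files. Of these targets, 14278 carried a clone or contig identifier, 73 a GenBank entry alone and 61 a text name or mnemonic. None of the GenBank entries matched the RefSeq gene table of the organism (assembly AplCal3.0), which pairs other accessions with symbols, and 2 target names, PC2 and FUR, matched symbols in it, so the names are those of the array design. The number of sample columns left unmapped was 0. Probes written as targeting the opposite strand of a contig numbered 6026 and were kept as separate targets. No target was named for sensorin, the textbook peptide of mechanosensory neurons in this animal, so the check of the labels planned with it was not run.

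Mean intensities were background-corrected with normexp (offset 50) on the local median background and normalized within each array by loess with a span of 0.3, with control spots at weight 0, in limma 3.58.1 under R 4.3.3. Ratios are given throughout as log2 of L7 over sensory cluster, the reverse of the deposited ratios. Control spots and spots with an outlier flag were left out, and saturated spots were kept. Spots of one probe were averaged. A probe was tested if it was well above background in at least 1 channel on at least 2 arrays, which left 20805 probes of 14322 targets and removed 323 probes. An intercept was fitted to the 3 log ratios with lmFit and eBayes and tested against 0, two-sided, with Benjamini-Hochberg adjustment over all tested probes and a threshold of 0.05. As both RNAs were on each array, the array is the pair. Fold changes of dim probes are understated by the offset. A probe saturated on every array in one channel has only a bound, given as the brighter channel's mean over the dimmer one's from channel values after loess and Aquantile normalization. These values are open to dye bias.

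Targets with different probes were represented by the probe of highest mean intensity A over the arrays. The 20 gene lists, patterns on target names, were fixed before the data were examined. A list was to be tested with at least 5 named members and none reached that number, so values of the members are given instead. A further 18 groups of targets were written after the target names were read and before any probe's difference was computed, and the 17 of them with at least 5 members were tested with camera (preset correlation 0.01, and an estimated correlation) and with fry for a shift in one direction and for differences in either direction. The rule for named genes took, among targets with a text name, those past the threshold with the largest change, and, where fewer than 10 passed in a direction, the smallest unadjusted p. As no target with a text name passed, 10 per direction are given by unadjusted p, as values. In addition, 1 GenBank entry and 1 clone identifier per direction, those with the largest change among probes past the threshold, were chosen after their values were seen.

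The fit was tested on simulated data drawn from the spread of the 20805 probes, with 200 changed probes in each of 10 runs. It called 38.2% of probes changed by 1 on the log2 scale, 89.1% of those changed by 2 and 98.6% of those changed by 4, and 3.84% of its calls were unchanged probes. In 100 runs, camera called a set of 8 shifted by 0.5 in 100 and an unshifted set in 2, and fry called them in 97 and 6. These set calls used an unadjusted p under 0.05, while the real groups were judged after adjustment over 17 groups. The counts are therefore not the power of the reported group tests. The simulated values followed the model of the fit, with the arrays alike, so the rates of calls hold under that model only. Multiplying the green signals of 200 bright probes by 4 moved their log2 ratio by a median of 2.05 after normalization.

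The alternatives were no background correction, the processed signals of the scanner software, median centring in place of loess, loess followed by scaling between arrays, the deposited series values, other filters on dim probes, saturated spots left out, an intensity trend with a robust prior, an ordinary test without variance sharing, separate channels without the array as a block, and leaving out each replicate. The mean over all probes of a target was added after the data were seen. Figures were drawn with matplotlib 3.10.9. The number of arrays limits the precision of all values.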

Results

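Messenger RNA of the L7 motor neuron was compared directly with that of a sensory cluster on 3 arrays of Aplysia californica transcripts, to ask which transcripts differ in level between a motor neuron and sensory neurons. The median signal was 181, 197 and 175 intensity units for L7 and 374.5, 470 and 194 for the sensory cluster on arrays 1, 2 and 3. The median signal of L7 was 4.60, 2.12 and 2.005 times that of the negative controls, and the median signal of the sensory cluster 6.65, 5.71 and 2.47 times. Between 92.4% and 98.5% of measured features were well above background in the L7 channel and between 94.3% and 98.7% in the sensory channel. Saturated features numbered 21, 2 and 28 in the L7 channel and 217, 400 and 160 in the sensory channel.

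Transcripts from 37 targets differed in level between the L7 neuron and the sensory cluster, 16 higher in L7 and 21 higher in the sensory cluster. Of these, 14 and 18 had at least 1 called probe that was saturated on no array. The target AF160191, a GenBank entry, was higher in L7 by 3.97 ± 0.22 on the log2 scale (SE, n = 3 arrays; limma adjusted p = 0.0285), a 15.7-fold difference, with log2 ratios of 3.45, 4.53 and 3.93 on the 3 arrays. With the processed signals of the scanner software its log2 ratio was 4.79, and it did not pass without replicate 2 (limma adjusted p = 0.0542) or replicate 3 (limma adjusted p = 0.229). All 3 probes of this target were higher in L7, between 2.72 and 3.97, and 2 of them passed the threshold. The clone target PEG003-C-229558, which has 1 probe, was higher in L7 by 4.96 ± 0.14 (SE, n = 3; limma adjusted p = 0.00964), a 31.1-fold difference, and did not pass without replicate 3 (limma adjusted p = 0.120) or after scaling between arrays (limma adjusted p = 0.175). In the sensory cluster, the target U57369 was higher, with a log2 ratio of −5.66 ± 0.46 (SE, n = 3; limma adjusted p = 0.0487) and values of −4.35, −6.62 and −6.02 on the 3 arrays. The 3 probes of that set lay between −5.66 and −4.51 and all passed, with the sensory channel saturated on 1 array for the probe given and on 2 arrays for the others, so that these differences are lower bounds on the arrays concerned. Without saturated spots the log2 ratio of the probe given was −5.19 and did not pass (limma adjusted p = 0.0887). It also did not pass without replicate 2 or 3 (limma adjusted p = 0.101 and 0.312), without background correction (0.0505) or without the filter on dim probes (0.0536). A further set of 3 probes for the same entry gave −3.39, −2.32 and −2.09, none past the threshold (the smallest limma adjusted p = 0.102). The clone target PEG003-C-224404 was at least 33.2-fold higher in the sensory cluster (limma adjusted p = 0.0116), as its sensory channel was saturated on all 3 arrays, and each of its 3 probes passed. It did not pass without replicate 3 (limma adjusted p = 0.120) or after scaling between arrays (limma adjusted p = 0.162). These 4 targets, of which the clones are given by shortened identifiers, are not paired with gene symbols in the files, and they were chosen after their values were seen.

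**Figure D1:**
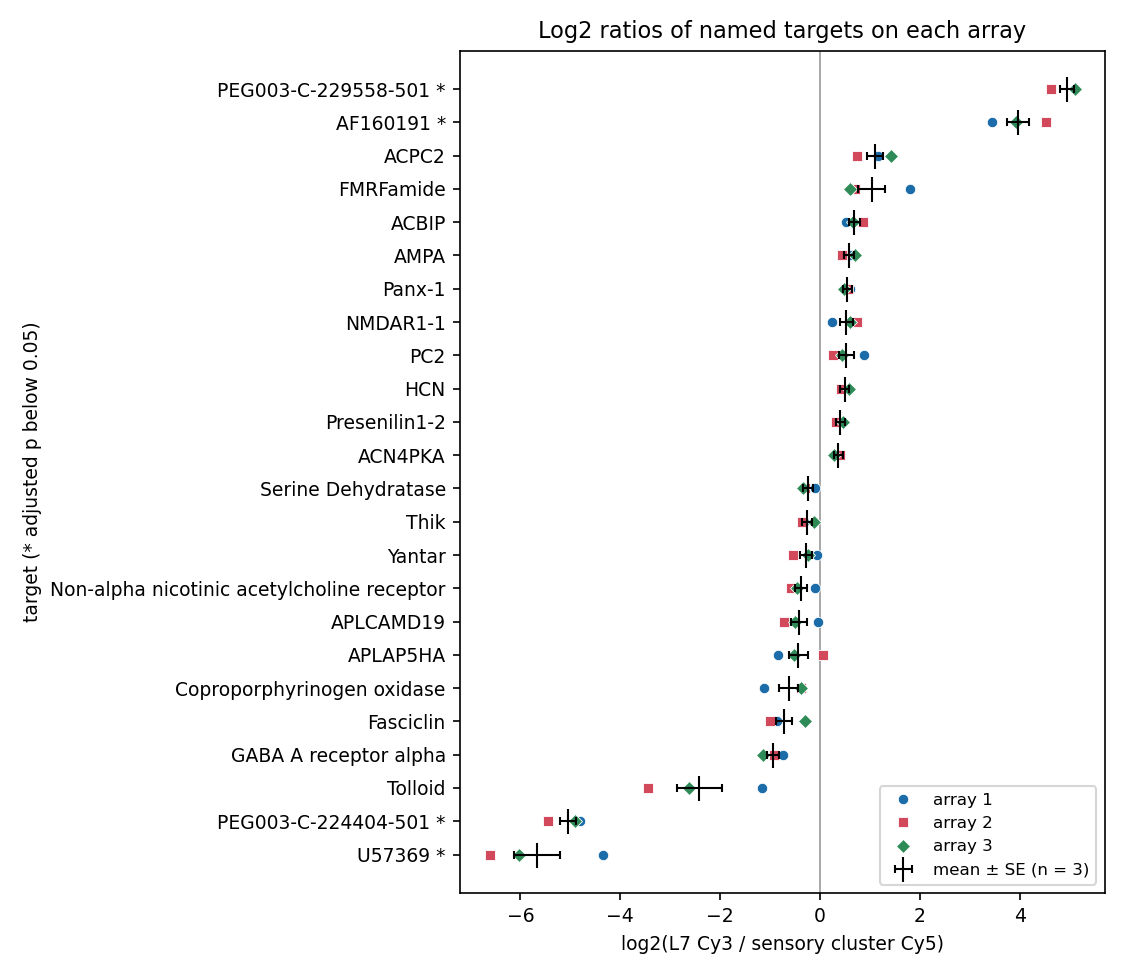
Log2 ratio of L7 (Cy3) over sensory cluster (Cy5) on the horizontal axis for each named target, with 1 symbol per array, and the mean with its SE (n = 3 arrays) in black. Asterisks mark the 4 targets with a limma adjusted p below 0.05, which lie between −5.66 and 4.96, while the 20 targets with a text name lie between −2.41 and 1.11.

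At the level of probes, 49 of 20805 passed the threshold in limma, 19 higher in L7 and 30 higher in the sensory cluster, and 48 of them had the same sign on all 3 arrays, while the other was measured on 2 arrays, with the same sign on both. The median log2 ratio was 2.24 over the 19 and −3.03 over the 30, and the smallest absolute value was 1.08. The called targets were 33 clone or contig identifiers and 4 GenBank entries. Of these entries, U50080 is in the group of targets with Lymnaea mnemonics described below. Of 24 called targets with at least 2 tested probes, 21 had all probes on the same side and 10 had at least 2 called probes. At an unadjusted p under 0.05, 3545 probes (17.0%) differed, 1584 toward L7 and 1961 toward the sensory cluster. A mean difference of at least 1 on the log2 scale with the same sign on all 3 arrays was seen for 458 probes, 220 toward L7 and 238 toward the sensory cluster. In the sensory channel, 11 of the 49 called probes were saturated on at least 1 array. Of these 11, 4 were among the 19 higher in L7, with log2 ratios between 1.08 and 1.18 and mean intensities of at least 15.27. The ratio of a probe clipped in the sensory channel alone is shifted toward L7. Of these 4, 3 were also saturated in the L7 channel on 1 or 2 arrays, where the ratio of 2 clipped signals does not settle a direction. Without saturated spots the count was 25, with 9 higher in L7 and 16 higher in the sensory cluster. Median centring in place of loess gave 551 probes, 70 higher in L7 and 481 higher in the sensory cluster, and the count was 509 without replicate 1, 7 without replicate 2 and 0 without replicate 3 (with 1281 probes at an unadjusted p under 0.05).

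**Figure D2:**
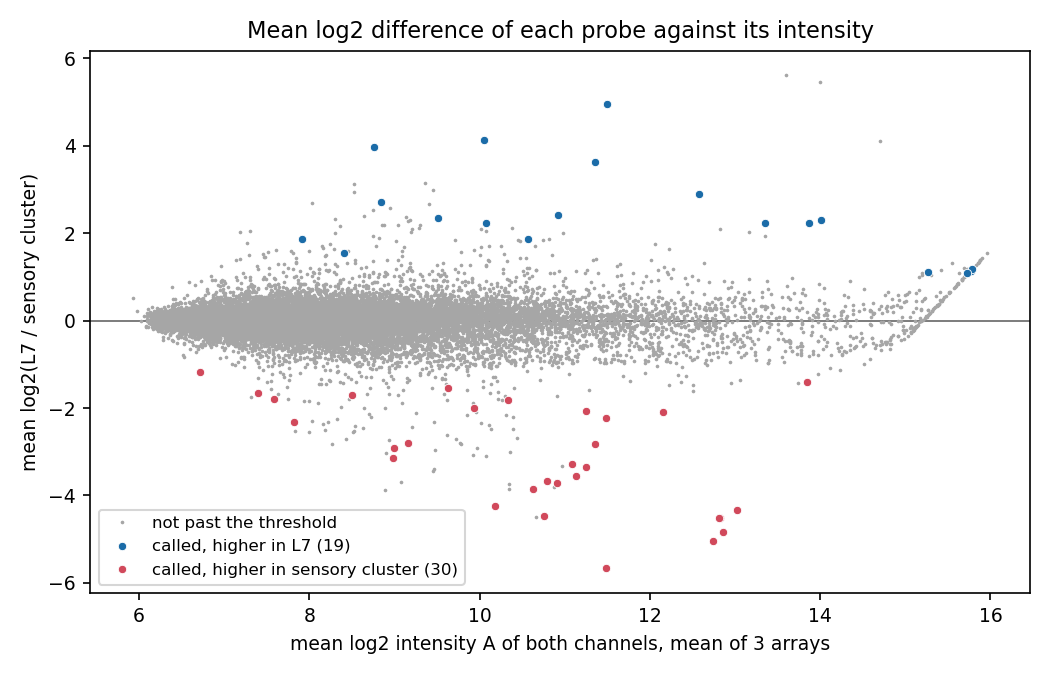
Mean log2 ratio of L7 over sensory cluster on the vertical axis against mean log2 intensity of both channels on the horizontal axis, for the 20805 tested probes (means of 3 arrays). Blue points are the 19 probes called higher in L7, red points the 30 called higher in the sensory cluster and grey points all others. The line of points rising to the right above an intensity of 15 holds probes saturated in the sensory channel.

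No target with a text name passed the threshold in limma over all probes, where the smallest adjusted p was 0.0828, or when adjusted over the text-named probes alone. At an unadjusted p under 0.05, 42 of their 182 probes differed. The values below are therefore not calls over all probes. Tolloid, the name of a secreted metalloprotease, had the largest difference, −2.41 ± 0.45 (SE, n = 3; limma adjusted p = 0.157), with −1.17, −3.44 and −2.63 on the 3 arrays and all 3 of its probes on the sensory side, between −2.82 and −1.28. Its value was −3.04 without replicate 1 (limma adjusted p = 0.00664), where 509 probes passed in place of 49, −1.90 without replicate 2 (adjusted p = 0.224) and −2.31 without replicate 3 (adjusted p = 0.654). It was the only named member of the list on plasticity signalling. The patterns of that list missed mnemonics such as ACN4PKA, so it does not cover every target of this kind.

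Among the named receptors for transmitters, the 3 members of the fixed list lay on both sides. The alpha subunit of a GABA A receptor had a log2 ratio of −0.94 ± 0.11, AMPA, a name of ionotropic glutamate receptors, 0.59 ± 0.10, and a non-alpha nicotinic acetylcholine receptor subunit −0.38 ± 0.13 (SE, n = 3 each). None passed over all probes, and all 3 passed when adjusted over the list alone (limma adjusted p = 0.00210, 0.00451 and 0.0353). That adjustment covers the 3 members only and not the other lists, and it leaves the last value equal to the unadjusted p. The 3 probes for the GABA A receptor disagreed, with 1 at 0.24, while the 3 AMPA probes lay between 0.51 and 0.59. For the nicotinic subunit, the other probes gave 0.0093 and −0.24. NMDAR1-1, an NMDA receptor subunit, had a value of 0.53 ± 0.13, and its other probes gave 0.0048 and 0.28. Of the named ion channels, 9 of 14 lay toward L7. HCN, the name of the hyperpolarization-activated cation channels and the single member of the fixed list on channels, pumps and gap junctions, had a value of 0.50 ± 0.09, and its other probes gave 0.24 and 0.33. Thik, a name of potassium channels with paired pore domains, had a value of −0.26 ± 0.10. The pannexin Panx-1 had a value of 0.55 ± 0.09, and its other probes gave 0.60 and 0.11. Of the pannexin targets, 4 of 5 lay toward L7, where Panx-3 counts as 2 targets from 1 entry, with 1 on each side (0.48 and −0.14).

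Named peptide precursors and processing enzymes lay mostly toward L7, 6 of 8, with a median log2 ratio of 0.43. PC2 counts as 2 of these targets because 1 entry has 2 probe sets. ACPC2, a separate entry also toward L7, bears PC2 in its mnemonic too, so the 6 may hold fewer distinct genes. The shift of the group did not pass in camera (adjusted p = 0.184, and adjusted p = 0.805 with an estimated correlation) or in fry (adjusted p = 0.161). The median was 0.11 after median centring, 0.29 without replicate 1, 0.63 without replicate 2 and 0.31 without replicate 3. Members of the group included ACPC2 at 1.11 ± 0.16, ACBIP at 0.69 ± 0.11 and PC2, prohormone convertase 2, at 0.53 ± 0.15 (SE, n = 3 each). The 3 probes ranged from 0.72 to 1.11 for ACPC2, from 0.15 to 0.69 for ACBIP and from 0.48 to 0.77 for PC2. In the fixed list of neuropeptides, FMRFamide, the precursor of the cardioexcitatory peptide, had a value of 1.03 ± 0.27 with 1.80, 0.71 and 0.60 on the 3 arrays, and passed only when adjusted over the list alone (limma adjusted p = 0.0288). That probe was saturated on 1 array in each channel, and its value was 0.29 after median centring. The other probes for FMRFamide gave 0.72 and −0.15. The second member, an entry named neuropeptide precursor, had a value of −0.15 ± 0.12.

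Adhesion molecules lay on both sides. Fasciclin, a cell adhesion protein, had a log2 ratio of −0.72 ± 0.17 and passed when adjusted over the list of 4 alone (limma adjusted p = 0.0368), and the 3 cadherins lay at −0.24, 0.19 and 0.26. Its 3 probes ranged from −0.72 to 0.23. APLCAMD19 had a value of −0.42 ± 0.16. The enzymes and transporter of transmitter handling in the fixed list did not pass in any case. Their values were 0.14 for a neurotransmitter transporter, 0.18 and −0.11 for nitric oxide synthases and 0.22 for histidine decarboxylase. That list missed the targets spelled Choline Acetyl Tranferase, at 0.0027 ± 0.11, and Dopamine Beta Hydroxlase, at 0.38 ± 0.11, neither past the threshold. Actin at 0.26 ± 0.40 and beta-tubulin at −0.10 ± 0.19, members of the cytoskeleton, varied between arrays more than they differed between the cells. Staufen, an RNA-binding protein, had a value of 0.25 ± 0.11. The markers of other cell types were Twitchin-like, a muscle protein, at 0.38 ± 0.15 and hemocyanin, the oxygen carrier of the blood, at 0.17 ± 0.11, neither past the threshold. For the other 10 fixed lists, no target name matched the patterns. Among them is the list on peptide processing, whose patterns missed short names such as PC2 and FUR, which are in the group of peptide precursors and processing enzymes.

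The remaining targets with a text name chosen by unadjusted p were Presenilin1-2 at 0.41 ± 0.09 and ACN4PKA at 0.37 ± 0.09 toward L7, and coproporphyrinogen oxidase at −0.62 ± 0.19, APLAP5HA at −0.43 ± 0.19, Yantar at −0.28 ± 0.13 and serine dehydratase at −0.24 ± 0.10 toward the sensory cluster (SE, n = 3 each). The probes of 3 of these disagreed in sign. The other probes of coproporphyrinogen oxidase gave 0.50 and 0.25 and the other probe of serine dehydratase 0.62, so that the means over probes were 0.042 and 0.19, toward L7. The other probes of APLAP5HA gave 0.17 and −0.37, and those of ACN4PKA 0.072 and 0.037.

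Many values of named targets depended on the normalization or on the probe. After median centring in place of loess they were 0.063 for Presenilin1-2, 0.11 for ACN4PKA, 0.18 for HCN, 0.25 for NMDAR1-1, 0.27 for Panx-1, −0.070 for Thik, −0.70 for Yantar, −1.27 for coproporphyrinogen oxidase and −1.30 for fasciclin. As means over probes they were 0.36 for ACBIP, 0.16 for ACN4PKA, 0.53 for FMRFamide, 0.27 for NMDAR1-1, −0.47 for the GABA A receptor, −0.21 for APLAP5HA and −0.15 for fasciclin.

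No group of targets with a shared kind of name passed in camera or in the test of fry for a shift in one direction, where the smallest adjusted p was 0.184 in camera and 0.0776 in fry. In the test of fry for differences in either direction, which does not compare a group with other targets, 5 of 17 groups passed. They were the targets with Lymnaea mnemonics (adjusted p = 0.00547), ion channels, pannexins, transmitter receptors, and peptide precursors with processing enzymes (adjusted p = 0.035 each), and some of these groups share members. For the Lymnaea mnemonics and the transmitter receptors, medians of 0.15 and 0.027 and means of −0.022 and −0.034 differed in sign. Lymnaea is a genus other than Aplysia, and how well the probes of that group measure Aplysia RNA was not tested. The Lymnaea group held 1 called target, U50080 at −2.095 ± 0.14 (SE, n = 3; limma adjusted p = 0.0415). Its other members lay between −0.31 and 0.42, and the group was not tested without U50080.

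The log2 ratios of the arrays ran the same way across probes, which are not independent replicates. Pearson's r was 0.350 for arrays 1 and 2, 0.528 for arrays 1 and 3 and 0.695 for arrays 2 and 3, and Spearman's rho was 0.290, 0.377 and 0.639. The sign was the same on all 3 arrays for 47.1% of probes, where 25% would come by chance. Between 2 probes of one target, Pearson's r of the mean log2 ratio was 0.579 and Spearman's rho 0.343 over 6225 targets. After median centring alone, the median log2 ratio was lower for brighter probes on each array. It was 0.22, 0.63 and 0.15 on arrays 1, 2 and 3 for probes with a mean intensity under 7, and −0.31, −1.16 and −0.57 for those between 12 and 13.

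**Figure D3:**
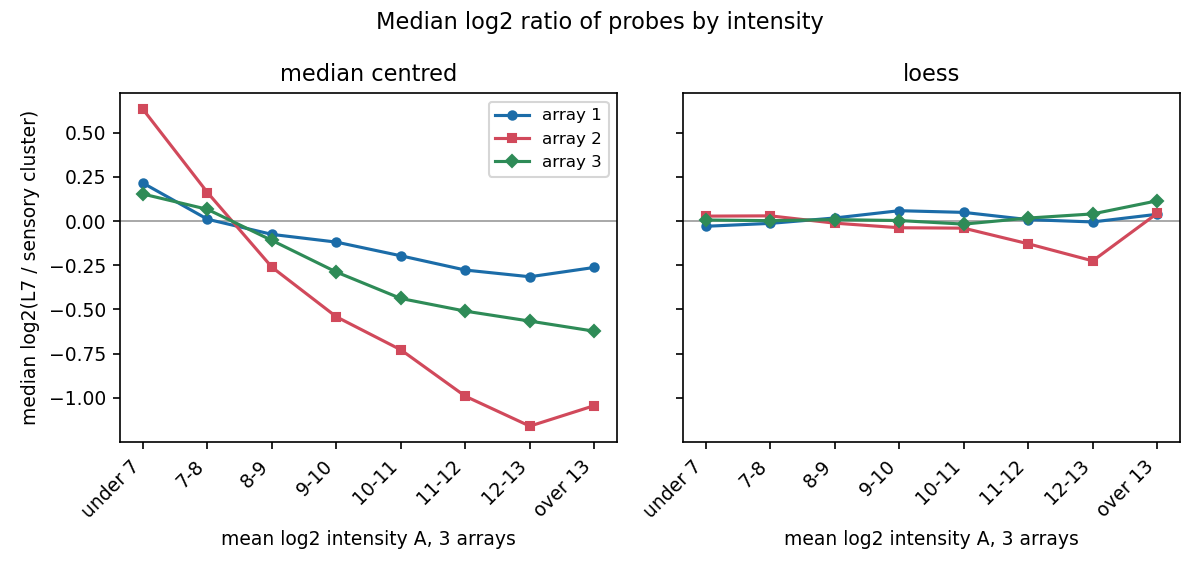
Median log2 ratio of L7 over sensory cluster on the vertical axis for probes in bins of mean log2 intensity on the horizontal axis, with 1 line per array, after median centring (left) and after loess (right). In the lowest bin the medians after centring are 0.22, 0.63 and 0.15, and they fall to −0.31, −1.16 and −0.57 between 12 and 13. After loess they lie between −0.225 and 0.115.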

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

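The mean over all probes of a target was chosen after seeing the data, and the other alternatives were fixed before the data were examined. The count of probes past the threshold, 49 (19 higher in L7 and 30 higher in the sensory cluster), moved with nearly every setting. It was 22 without background correction (6 and 16), 139 with the processed signals of the scanner software (57 and 82), 139 with the deposited series values (57 and 82), 551 after median centring (70 and 481), 0 after scaling between arrays (0 and 0, with 4075 probes at an unadjusted p under 0.05), 31 without the filter on dim probes (9 and 22), 64 with probes above background on all 3 arrays (28 and 36), 25 with saturated spots left out (9 and 16), 96 with an intensity trend and a robust prior (47 and 49) and 0 in an ordinary one-sample test (0 and 0, with 1704 probes at an unadjusted p under 0.05). With separate channels and no replicate block, so that the pairing by array was dropped, it was 29 (5 and 24), of which 22 were among the 49. Leaving out 1 replicate gave between 0 and 509 probes, between 0 and 191 higher in L7 and between 0 and 318 higher in the sensory cluster. The 49 were all among the 509 found without replicate 1, and 45 of them were among the 139. The means over probes of a target gave 43 targets (22 and 21) of 14322. All of the 49 that could be measured kept their direction, 41 of 41 without saturated spots, 48 of 48 under 4 settings and 49 of 49 under the others, and the target means were not compared in this way. Each of the 49 had the same sign on every array that measured it. Leaving out a replicate, or changing only the filter or the test, therefore could not turn the direction, and those settings are no test of it. Across probes, which are not independent replicates, the correlations of arrays 1 and 2, 1 and 3, and 2 and 3 were 0.465, 0.567 and 0.752 after median centring.

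AF160191 lost its call in an ordinary test, after scaling and without replicate 2 or 3 (limma adjusted p = 0.0542 and 0.229), U57369 also without background correction, without the filter and without saturated spots, and both clone targets in an ordinary test, after scaling and without replicate 3. PEG003-C-224404 has no value once saturated spots are left out. Some values of targets without a call passed elsewhere, such as the GABA A receptor with the processed signals (adjusted p = 0.0378) and ACPC2, fasciclin and coproporphyrinogen oxidase after median centring. The peptide precursor group passed with separate channels (camera adjusted p = 0.00805) and without replicate 2 (camera adjusted p = 0.00723), but not with an estimated correlation (camera adjusted p = 0.805). The sign of 2 named targets turned in the mean over their probes, to 0.042 for coproporphyrinogen oxidase and 0.19 for serine dehydratase. Median log2 ratios of groups, none past the threshold, turned as follows. Median centring gave −0.027 for ion channels, −0.037 for transmitter receptors, −0.31 for adhesion and structural proteins, −0.051, −0.0016 and −0.22 for 3 groups of clones and −0.075 for contigs. Leaving out replicates gave −0.043 to 0.071 for transmitter receptors, −0.17 to 0.078 for adhesion and structural proteins, −0.053 to 0.074 for a group of clones and −0.021 to 0.014 for contigs. The means over probes gave −0.040 and 0.038 for 2 groups of clones and −0.00016 for contigs. The check with sensorin was not run, as no target bears that name. Signal over background was lowest for L7 on array 3, where the median signal was 2.005 times that of the negative controls, which limits dim probes.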

Other observations

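All tests in this part were chosen only after the results they bear on were seen. Probe sequences were read in their forward frames to see what the targets encode, without naming genes from them. Each of the 3 probes of AF160191 encodes 2 phenylalanines, a glycine and 2 lysines in a row, the form of a peptide that is amidated and cleaved, in stretches such as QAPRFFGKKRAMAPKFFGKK. The probe of PEG003-C-229558, the clone target named above as higher in L7, encodes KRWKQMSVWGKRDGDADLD, with such a site after VW. The site was not confined to transcripts higher in L7. Of 9 probes that encode it and have a log2 ratio of at least 1 in size with the same sign on all arrays, 6 were toward L7 and 3 toward the sensory cluster, and of 4 called probes, 3 and 1, the last a contig at −1.82 (limma adjusted p = 0.0273). The 6 include the 3 probes of AF160191. The other probes toward the sensory cluster, at −3.09 and −2.15 (limma adjusted p = 0.106 and 0.249), are written as targeting the opposite strand. On the sensory side, a probe of PEG003-C-224404 encodes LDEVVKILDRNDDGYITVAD, which holds the pattern of a calcium-binding EF-hand loop. That pattern occurred in the forward frames of 10 tested probes and on the opposite strand of 0.

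Textbook peptides were searched in the same way. The FMRFamide sequence followed by glycine was encoded by 5 tested probes and by none on the opposite strand. Besides the 3 probes named FMRFamide, 2 contig probes encoded it, with log2 ratios of 0.99 and 0.73, and mean log2 intensities of 15.16 and 14.51. The myomodulin motif was found in 2 probes of one entry, at −0.43 and −0.23, and neither passed the threshold. The motifs used for sensorin, small cardioactive peptide and egg-laying hormone were encoded by 0 tested probes. Targets probed on both strands numbered 2430, and the log2 ratios of the 2 strands had a Pearson's r of 0.182 and a Spearman's rho of 0.110 across targets. Of the 9 targets with an absolute difference of at least 1 on both strands, 0 were on opposite sides.

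Targets whose probes encode an amidation and cleavage site reached a log2 difference of 1 with the same sign on all arrays in 8 of 165 cases (4.85%), against 2.46% of the other targets. One hypothesis is that transcripts of peptide precursors may differ more often between these cells. The odds ratio over targets was 2.02 (95% interval 0.851 to 4.13, Fisher's exact test p = 0.0694), and 1.52 (0.544 to 3.41) without the 2 targets that prompted the test, and both intervals include 1. Within 8 bins of intensity, with those 2 targets kept, the odds ratio over targets was 2.38 (1.14 to 4.97). That interval lies above 1, but the binned test was not run without the 2 targets that prompted it. It therefore adds no support to the hypothesis. Over probes the odds ratio was 2.48 (1.11 to 4.87), and 3.02 (1.5 to 6.07) within the bins. These also hold the probes of those 2 targets, and probes of one target are not independent. The same site on the opposite strand gave 0.477 (0.0119 to 2.75). The opposite strand keeps the GC content of a probe but exchanges its complementary bases, so it is no full control for base composition. The interval is also too wide to exclude composition. The hypothesis on peptide precursors and base composition both stay open.

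Array 1 correlated less with arrays 2 and 3 than these did with each other. Array 1 also had 1294 spots (3.08%) with an outlier flag, against 14 and 13 on arrays 2 and 3, and these spots were left out. Noise of the single spots that remained is argued against as the whole cause. Pearson's r between 2 probes of one target was 0.666 on array 1, 0.423 on array 2 and 0.640 on array 3, across 6069 targets. The r of the arrays corrected for disagreement between the 2 probes was 0.423 for arrays 1 and 2, 0.595 for arrays 1 and 3 and 0.760 for arrays 2 and 3. The last exceeded the larger of the others by 0.166 (bootstrap interval 0.0966 to 0.228). Ratios of probes with large differences on the other arrays were smaller on array 1. Such probes had a mean difference of at least 1 with the same sign on the other arrays. Their median size was 0.47 on array 1 against 1.25 on the others, 1.17 against 1.37 for array 2 and 1.10 against 1.28 for array 3. Choosing probes by the other arrays shrinks the values of an array more, the less it correlates with them. These values therefore cannot tell how much of the smaller size comes from the choice of probes. Over all tested probes, the SD of log2 ratios was 0.42, 0.59 and 0.46 on arrays 1, 2 and 3. One factor of compression leaves the corrected r unchanged, and is argued against as the cause of the lower correlation by the same difference of 0.166. Probe GC content is argued against, as it accounted for 1.63% of the variance of array 1's deviation from the mean of arrays 2 and 3. The median of the negative controls was also lower on array 1. It was 39.46 in the L7 channel against 93.05 and 87.3 on arrays 2 and 3, and 56.3 in the sensory channel against 82.35 and 78.55. Differences between animals, in the cells collected, in labelling or in how the arrays were processed and scanned stay open and may act together.

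After median centring alone, 481 of 551 called probes were higher in the sensory cluster. An intensity curve of the dyes, the background or the amplification needs ratios that are lower for bright probes, and over all probes the median was lower between intensities of 12 and 13 than under 7 on 3 of 3 arrays. Transcripts that are more abundant in the sensory cluster predict the same values. With 0 arrays that carry the dyes exchanged, these cannot be told apart. Ratios of bright probes depend on which is assumed, since loess removes either.

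The fit was repeated with the sign of 1 array turned, which makes 4 patterns with the real one, too few for a share under 0.05. The real pattern gave 49 probes and the highest of the others 0, so that 1 pattern reached the real count. Over the 70 probes with a mean intensity above 15 and the sensory channel saturated on all 3 arrays, the log2 ratio and the intensity had a Pearson's r of 0.9996 across probes. That value follows from the choice of probes. With the sensory signal at its ceiling, the ratio and the intensity both rise with the L7 signal alone.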
